A study of Danio rerio with 12 samples.

How the data were processed

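The gut bacteria of zebrafish (Danio rerio) aged 16 weeks were measured by sequencing the V3-V4 part of the bacterial 16S rRNA gene, a marker whose sequence differs between bacterial groups. Per the labels' protocols, fish were kept for 21 days in water with polystyrene particles of 100 nm, 5 µm or 200 µm at 500 µg/L, renewed every 2 days, or without particles. DNA was isolated from the intestinal contents with a DNeasy Blood & Tissue kit, and libraries were sequenced on an Ion S5 XL instrument, per the labels' protocols. Cutadapt 1.9.1 is named in the submitters' processing notes. The clustering into operational taxonomic units (OTUs), the taxonomy database, chimera removal and any thinning of reads to equal depth are not given in the sources used here.

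The authors deposited 1 table per library, which gives for each of 2228 OTUs its fraction of the library and its taxonomy. All 12 tables listed the same OTUs, and the fractions of each library summed to 100% of it. The smallest share above 0 was 0.00262% in each of the 12 libraries, and every other share was a whole multiple of it, with a largest deviation of 2e-11. Read counts were not used here, so the depth behind each share is unknown and no interval or detection limit that needs it is given. An OTU at 0 is therefore described only as listed at 0.

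Libraries were grouped by the particle size in the labels, with 3 libraries in each of 4 groups. The series design speaks of separate trials, but nothing says whether a library came from 1 fish or several. The p-values measure the spread between these libraries, which may be partly technical.

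Shares were multiplied by 100 and summed by genus, and an OTU without a genus was summed under its lowest named rank ("unclassified" before the rank). Of the 2228 OTUs, 943 had a genus name. Genera with a mean share of at least 0.01% that were listed above 0 in at least 3 libraries, 267 in all, were tested with limma 3.58.1 in R 4.3.3 on log2(percent + 0.01). All 12 libraries entered one fit of group means, with moderated variances that follow the mean level (eBayes with trend). Adjusted p-values are Benjamini-Hochberg values over the genera of a comparison, with a threshold of 0.05. Log2 differences are on the log2(percent + 0.01) scale, which understates the change of rare genera. The 382 OTUs that met the same filter were tested in the same way.

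Community composition was tested by the pseudo-F of a permutational multivariate analysis of variance on Bray-Curtis distances of the genus shares, exact over all 15400 distinct splits of the 12 libraries into 4 groups of 3. Spread within groups was tested by an F over the distances of libraries to their group's centroid, with centroids made anew in each of those splits. A version that kept the real distances and shuffled them was computed first. It was set aside because it passed 0.05 in 20.8% of 1000 simulated unchanged data sets, against 4.6% for the version used, and both values are given. The Shannon index (natural log), the Gini-Simpson index, the number of OTUs above 0, phyla with a mean share of at least 0.1% and summed taxon lists were tested by an F, exact over the same 15400 splits. The difference between exposed and unexposed libraries was tested 2-sided over the 220 choices of 3 libraries. Phyla and lists were tested on log2(percent + 0.01), with Benjamini-Hochberg adjustment within each family. An exact test of 3 libraries against 3 has 10 splits and cannot go below p = 0.1. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

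The tests, filters, 11 taxon lists and the rule for naming taxa were fixed before the data were examined. The rule takes the 10 most abundant genera, the 8 most abundant phyla, any genus holding at least 10% of a library, and members of lists whose group test passed. For each exposed group against control it takes the called genera with a mean share of at least 0.1% in either group, filled up to 10 by the lowest unadjusted p. For the other contrasts it takes 5 higher and 5 lower genera in the same way. The lists covered zebrafish gut core genera, opportunistic fish pathogens, lactic acid bacteria, gut anaerobic fermenters, reagent contaminants, plastic and aromatic degraders, biofilm and plastisphere genera, nitrifiers and aquarium water genera, spore-forming Bacilli and Clostridia, animal intracellular and symbiont genera, and organelle and photosynthetic reads. The last list had 0 detected members and was not tested. Lists match names only, so organelle reads filed under other names would not be found. Lists of aphid symbionts and of pig airway genera were written after the shares had been seen.

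The limma step was tested on simulated data for the 267 genera of the 100 nm comparison, with 60 genera changed in each of 50 simulations. It called 10.3% of genera changed 4-fold, 59.9% of those changed 16-fold and 89.1% of those changed 64-fold. It called 0.812% of unchanged genera in these runs, and 0.00749% of genera where nothing was changed. The simulated log values were drawn from normal distributions, independently for each genus, with no shares at 0 and no fixed total. The real shares differ in these ways, so these rates may not hold for them. Alternatives covered the pseudocount, the abundance filter, a centred log ratio, the variance model, library weights, taxonomic level, the distance, the replicate number as a block and leaving out each library. Added after seeing the data were fits without 18 OTUs of unidentified Cyanobacteria, without Bradyrhizobium, unclassified Xanthobacteraceae and Buchnera, without Cetobacterium, and without the control libraries led by Bradyrhizobium or Buchnera.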

Results

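The relative abundance of gut bacteria was compared between zebrafish exposed to polystyrene particles of 100 nm, 5 µm or 200 µm and unexposed fish, with 3 libraries in each of 4 groups. The question was whether particle exposure, and particle size, went with a different intestinal community. Libraries listed between 215 and 929 OTUs above 0, and 46 of the 2228 OTUs were above 0 in all 12 libraries. Read depth is unknown, since no read counts were used.

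Cetobacterium, an anaerobic member of the Fusobacteria common in the guts of freshwater fish, was the most abundant genus, with a mean of 29.8% over the 12 libraries. It held 19.2% ± 30.9 (SD, n = 3) of the control libraries, 15.7% ± 20.8 of the 100 nm libraries, 63.3% ± 19.0 of the 5 µm libraries and 21.1% ± 26.1 of the 200 µm libraries. Plesiomonas and Vibrio, aquatic Gammaproteobacteria found in fish guts, averaged 4.75% and 3.62%, and unidentified Erysipelotrichaceae averaged 3.70%. The file places this last taxon in the Firmicutes, but 2 of its 5 OTUs carry a species name of Cetobacterium, and they held between 11.7% and 98.7% (median 95.6%) of the taxon in a library. Other abundant genera held large shares of few libraries. Bradyrhizobium, a soil and root-nodule genus, held 70.3% of control replicate 2 and 9.19% of 100 nm replicate 2. Buchnera, the obligate symbiont of aphids, held 31.5% of control replicate 3 and 2.52% of 200 µm replicate 1, and at most 0.0183% of each other library. Sphingomonas, an aerobic genus of water and soil, held 24.8% of control replicate 3. Moraxella, a genus of mammalian mucosa, held 13.5% and 27.7% of 100 nm replicates 1 and 3, and Actinobacillus, of the same habitat, held 10.3% of replicate 3. Lactobacillus, a lactic acid bacterium, held 18.8% of 100 nm replicate 2, and Streptococcus held 12.7% and unidentified Cyanobacteria 10.5% of 200 µm replicate 1. Vibrio held 22.1% and Plesiomonas 14.6% of 200 µm replicate 2, and unidentified Erysipelotrichaceae reached 10.7% in 5 µm replicate 1.

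**Figure D1:**
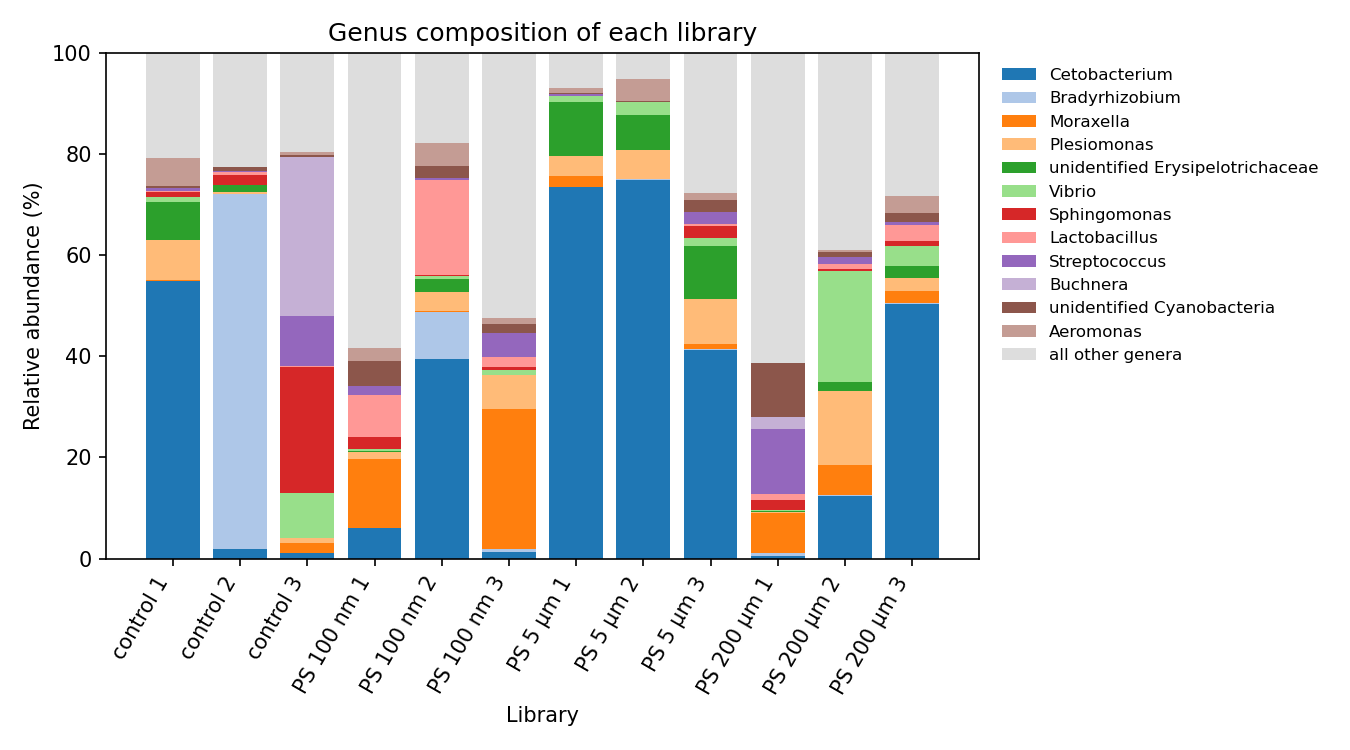
Relative abundance in percent (vertical axis) of the most abundant genera in each of the 12 libraries (horizontal axis, group and replicate number), with all other genera in light grey. Cetobacterium led all 3 libraries of the 5 µm group, at 73.5%, 74.9% and 41.3%, whereas the 3 control libraries were led by Cetobacterium (54.9%), Bradyrhizobium (70.3%) and Buchnera (31.5%).

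Proteobacteria made up 60.7% ± 35.5 (SD, n = 3) of the control libraries, 37.4% ± 16.1 of the 100 nm, 17.4% ± 5.84 of the 5 µm and 37.7% ± 18.6 of the 200 µm libraries. Fusobacteria, nearly all Cetobacterium, made up 19.3% ± 30.9, 15.9% ± 20.7, 63.4% ± 18.9 and 22.0% ± 25.2 in the same order. Firmicutes made up 10.5% ± 4.24, 24.1% ± 4.06, 12.9% ± 5.72 and 18.1% ± 5.88. Bacteroidetes, which include many anaerobes of animal guts, made up 2.45% ± 2.12, 8.55% ± 4.17, 0.911% ± 0.791 and 9.12% ± 8.31. Actinobacteria averaged 4.18%, Cyanobacteria 2.25%, Tenericutes 0.662% and Acidobacteria 0.485% over all libraries. Of 13 phylum labels tested over the 4 groups, 1 passed, the file's own label of unidentified bacteria (exact permutation F, p = 0.00305, adjusted p = 0.0397). Its shares were 0.0986% ± 0.0178 in control, 0.365% ± 0.406 in 100 nm, 0.0174% ± 0.0258 in 5 µm and 0.534% ± 0.214 in 200 µm libraries. It is no single lineage, since 12 of its 25 OTUs were Campylobacterales. The count was 0 without any 1 of the control or 200 µm libraries, 100 nm replicate 3 or 5 µm replicates 1 and 2, and 2, with Tenericutes, without 100 nm replicate 2. Bacteroidetes and Tenericutes had exact p = 0.0292 and p = 0.0205 before adjustment and 0.126 after it. For exposed against unexposed libraries none of the 13 passed, with a lowest exact p of 0.0409 for Tenericutes and an adjusted p of 0.502.

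Bray-Curtis distances, which run from 0 for equal to 1 for disjoint communities, averaged 0.639 within groups and 0.708 between groups. The 4 groups did not differ in composition by more than the spread between libraries (pseudo-F = 1.49, R2 = 0.358, exact permutation p = 0.151). The exact permutation p was 0.0336 with Aitchison distances, 0.0482 with square-root shares, 0.0203 without Cetobacterium and 0.0323 without control replicate 1, so this result depends on these choices. Between pairs of groups, R2 was highest for 100 nm against 5 µm at 0.471, with an exact p of 0.1, which is the smallest that 3 against 3 allows. R2 was 0.394 for 5 µm against 200 µm, 0.310 for control against 5 µm, 0.221 for control against 100 nm, 0.165 for control against 200 µm and 0.150 for 100 nm against 200 µm.

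The control libraries lay farthest from their group's centroid, at a distance of 0.512 ± 0.0216 (SD, n = 3), and the 5 µm libraries nearest, at 0.172 ± 0.0666. The 100 nm and 200 µm libraries lay at 0.386 ± 0.0904 and 0.414 ± 0.0542. These distances did not differ past the threshold (F = 15.4, exact permutation p = 0.0944). Shuffling the same distances over the libraries gave p = 0.00195, in a permutation test that passed too often on simulated unchanged data.

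**Figure D2:**
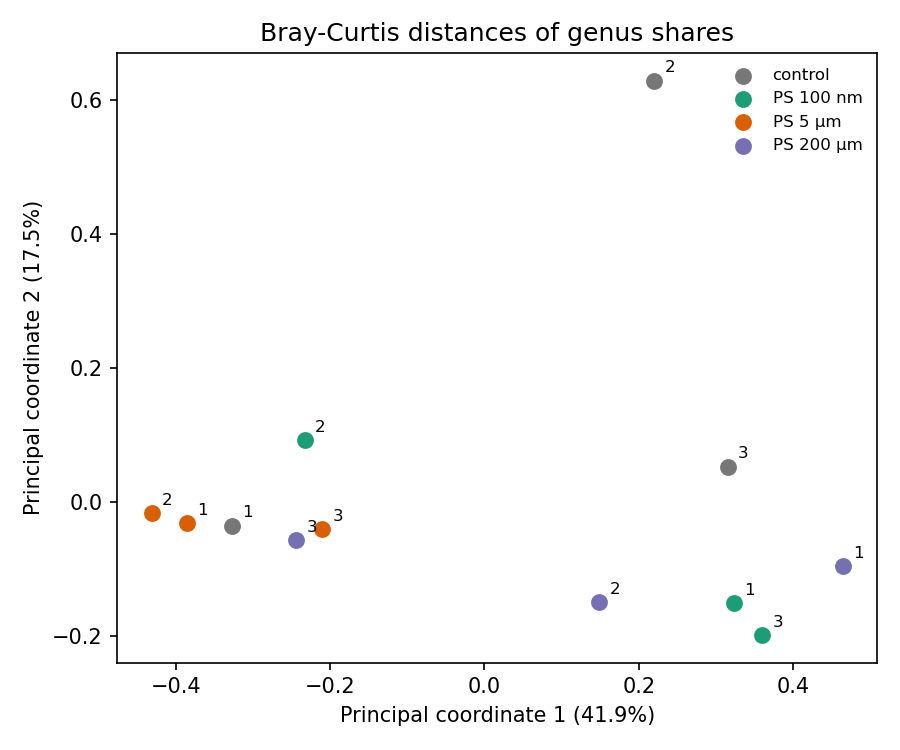
Principal coordinates of the Bray-Curtis distances between the genus profiles of the 12 libraries, with axis 1 holding 41.9% and axis 2 holding 17.5% of the positive eigenvalues. Points are libraries, coloured by group and marked by replicate number. The mean Bray-Curtis distance was 0.285 between the 5 µm libraries and 0.887 between the control libraries.

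The Shannon index was 2.55 ± 0.565 (SD, n = 3) in control, 4.10 ± 1.08 in 100 nm, 2.61 ± 0.918 in 5 µm and 4.16 ± 0.814 in 200 µm libraries (exact permutation F, p = 0.0966, adjusted p = 0.287). The Gini-Simpson index was 0.755 ± 0.221, 0.943 ± 0.0420, 0.840 ± 0.0739 and 0.938 ± 0.0379 in the same order, with an exact permutation p of 0.191 and an adjusted p of 0.287. The libraries listed 424 ± 55.3, 491 ± 154, 339 ± 198 and 552 ± 332 OTUs, with an exact permutation p of 0.681. For exposed against unexposed libraries the 2-sided exact p was 0.145 for the Shannon, 0.0727 for the Gini-Simpson index and 0.800 for the OTU number, and adjusted p-values were 0.218, 0.218 and 0.800. These differences depend on few taxa and on control replicate 2. The Gini-Simpson index of the control libraries was 0.880, 0.50 and 0.884, and the difference between exposed and control means went from 0.152 to 0.025 without control replicate 2, and that of the Shannon index from 1.07 to 0.746. With Bradyrhizobium, unclassified Xanthobacteraceae and Buchnera left out, the differences were 0.0045 for the Gini-Simpson and 0.034 for the Shannon index.

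**Figure D3:**
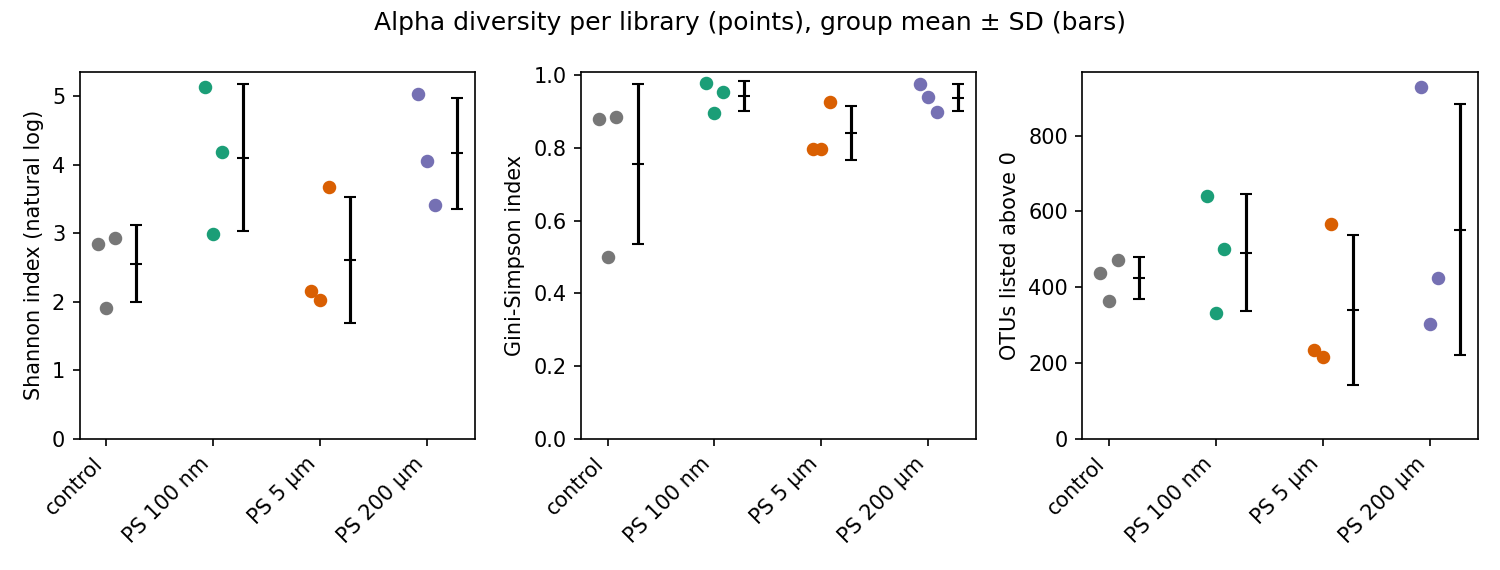
Shannon index, Gini-Simpson index and number of OTUs listed above 0 (vertical axes) for each library (points), with the mean and SD of each group of 3 (black bars), by exposure group (horizontal axes). All 3 control libraries lay below all 3 libraries at 100 nm and all 3 at 200 µm in the Shannon and the Gini-Simpson index with all taxa counted, and the OTU numbers run from 215 in a 5 µm library to 929 in a 200 µm library.

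In the 100 nm libraries, Romboutsia, unclassified Rikenellaceae, Mycoplasma and Actinobacillus held larger mean shares than in control, but none of 267 genera passed the limma test after adjustment. Romboutsia, a spore-forming gut anaerobe, held 2.32% ± 2.08 (SD, n = 3) against 0.0288% ± 0.0146 in control, a log2 difference of 5.38 with a 95% interval of 2.55 to 8.20 and an adjusted p of 0.0790. Unclassified Rikenellaceae, a family of gut anaerobes, held 0.646% ± 0.637 against 0.0113% ± 0.0196, a log2 difference of 4.89 with the same adjusted p. Mycoplasma, which lacks a cell wall, held 1.99% ± 2.27 against 0.0410% ± 0.0687, and Actinobacillus held 4.84% ± 5.17 against 0.0672% ± 0.110, with adjusted p-values of 0.0936 and 0.219. In 100 nm replicate 3, an OTU with the species name Mycoplasma hyorhinis in the file held 4.42%, of 4.52% Mycoplasma. An Actinobacillus OTU with the species name [Haemophilus] parasuis held 8.81% of that library, of 10.3% Actinobacillus. Moraxella held 13.9% ± 13.7 against 0.668% ± 1.08, and Lactobacillus 9.73% ± 8.47 against 0.389% ± 0.232, with log2 differences of 4.80 and 4.24 and adjusted p-values of 0.451 and 0.295. Paraclostridium, another spore former, held 0.175% ± 0.142 and was listed at 0 in all 3 control libraries, as was unclassified Actinobacteria at 0.148% ± 0.187. Butyricicoccus and unclassified Moraxellaceae completed the 10 genera of lowest p, all of them higher, and 5 of them, picked by their p, had shares that did not overlap between the groups. Over all 267 genera 24 (8.99%) did so, where chance gives 10% without ties and can give less where libraries tie at 0. At an unadjusted p under 0.05 there were 23 genera, 20 of them higher, and with the centred log ratio 23, 11 of them higher. With only the genera of at least 0.1% mean share, limma called 4 (Actinobacillus, Mycoplasma, Romboutsia and unclassified Rikenellaceae), without the variance trend 2, and without 100 nm replicate 2 it called 3. A list of pig airway genera, written after the shares had been seen, held 23.1%, 0.884% and 52.4% of the 100 nm libraries and 0.740%, 0.398% and 12.2% of the control libraries.

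In the 5 µm libraries Cetobacterium held 63.3% ± 19.0 (SD, n = 3) against 19.2% ± 30.9 in control, a log2 difference of 3.71 with a 95% interval of -0.55 to 7.97. Unidentified Erysipelotrichaceae held 9.40% ± 2.04 against 2.99% ± 3.95, and Shewanella, a facultative anaerobe of water and fish guts, held 2.14% ± 0.691 against 0.413% ± 0.385. Sphingomonas held 0.825% ± 1.37 against 9.21% ± 13.5, with the lowest unadjusted limma p among the genera named here, 0.0189. Buchnera held 0.0122% ± 0.00545 against 10.5% ± 18.2, and unclassified Xanthobacteraceae 0.0148% ± 0.0213 against 2.39% ± 4.11, where the control means came mostly from 1 library each. Without control replicate 3 the log2 difference of Buchnera went from -3.50 to 0.0036. Serratia held 0.0288% ± 0.0163 against 0.379% ± 0.463, Rickettsia was listed at 0 in the 5 µm libraries against 0.536% ± 0.922, and Shinella and Intrasporangium had log2 differences of 2.27 and 2.17. None of the 267 genera passed limma, with adjusted p-values of 1 for all 10 genera named, and 2 were under an unadjusted p of 0.05, none of them higher, against 6, 5 of them higher, with the centred log ratio. With library weights limma called 3 genera, Sphingomonas, Rubrobacter and unclassified Enterobacteriaceae, all lower at 5 µm. The last pair were named here after their values were seen. The weights were 7.27 and 3.38 for 5 µm replicates 1 and 2 and 0.423 for replicate 3, so replicates 1 and 2 made up most of the 5 µm mean.

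In the 200 µm libraries, Prevotella, Actinobacillus, Mycoplasma and Moraxella held larger mean shares than in control, and none of the 267 genera passed limma. Prevotella, an anaerobe of animal guts and mouths, held 0.460% ± 0.508 (SD, n = 3) against 0.0113% ± 0.0196, a log2 difference of 4.25 with an adjusted p of 0.424. Actinobacillus held 1.39% ± 1.51 against 0.0672% ± 0.110, Mycoplasma 0.395% ± 0.102 against 0.0410% ± 0.0687 and Moraxella 5.37% ± 2.78 against 0.668% ± 1.08. Unclassified Rikenellaceae held 0.188% ± 0.108, and Proteus, an enteric bacterium, 0.283% ± 0.378 against 0.00611% ± 0.00658. The soil genera Devosia, Rhodanobacter and Bryobacter held 0.10% ± 0.104, 0.167% ± 0.157 and 0.161% ± 0.0791, and each was above 0 in 1 control library. Unclassified members of an unidentified class of Gammaproteobacteria had a log2 difference of 3.15. All 10 genera, picked by their p, had shares that did not overlap between the groups. Over all 267 genera 33 (12.4%) did so, where chance gives 10% without ties and can give less where libraries tie at 0. At an unadjusted p under 0.05 there were 25 genera, all of them higher, and with the centred log ratio 22, 14 of them higher.

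With all 9 exposed libraries against control, none of the 267 genera passed limma, and the adjusted p was 0.938 for each genus named. Mycoplasma held 0.825% ± 1.44 (SD, n = 9) of the exposed libraries, Actinobacillus 2.21% ± 3.37 and Moraxella 6.75% ± 9.0, with log2 differences of 3.60, 4.19 and 3.71. Unclassified Rikenellaceae and Subdoligranulum, gut anaerobes, had log2 differences of 2.70 and 2.37. Serratia, Sphingomonas, unclassified Enterobacteriaceae, Rickettsia and Buchnera had log2 differences of -2.73, -2.89, -2.16, -2.18 and -2.74. Those of Rickettsia and Buchnera turned to 0.12 and 0.76 without control replicate 3. At an unadjusted p under 0.05 there were 7 genera, 5 of them higher, and with the centred log ratio 18, 6 of them higher.

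Between particle sizes, 3 genera passed limma for the 5 µm against the 100 nm libraries. Shewanella was higher in the 5 µm libraries, at 2.14% ± 0.691 (SD, n = 3) against 0.0288% ± 0.0250, a log2 difference of 5.98 with a 95% interval of 2.93 to 9.02. Lactobacillus was lower, at 0.125% ± 0.137 against 9.73% ± 8.47, a log2 difference of -6.16 with an interval of -9.20 to -3.12. Unclassified Rikenellaceae was lower too, at 0.00611% ± 0.0106 against 0.646% ± 0.637, a log2 difference of -5.10 with an interval of -7.65 to -2.55. Each had an adjusted limma p of 0.0425. Over all 267 genera 31 (11.6%), these 3 among them, had shares that did not overlap between the groups, where chance gives 10%. Among genera that did not pass, unidentified Erysipelotrichaceae had a log2 difference of 5.23, Cetobacterium 3.14, Bosea 2.49 and Intrasporangium 2.06, and Romboutsia -4.80, Paraclostridium -3.58 and Parabacteroides -3.50. At an unadjusted p under 0.05 there were 32 genera, 3 of them higher, and with the centred log ratio 17, 10 of them higher. The count went from 3 to 0 without control replicate 1, any 100 nm replicate, 5 µm replicate 1 or 2, or 200 µm replicate 2, to 2 without 5 µm replicate 3, and to 0 with a pseudocount of 0.001% or 0.1%. Control replicate 1 and 200 µm replicate 2 enter only through the shared spread and the filter, with 255 genera tested without the first and 256 without the second. The log2 differences were then as before, and the adjusted limma p of each of the 3 genera was 0.0707 and 0.0657. Over all alternatives the log2 difference ran from -7.04 to -5.03 for Lactobacillus (adjusted p from 0.00795 to 0.284), from 4.09 to 7.30 for Shewanella (0.00316 to 0.284) and from -7.47 to -2.49 for unclassified Rikenellaceae (0.00984 to 0.284).

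**Figure D4:**
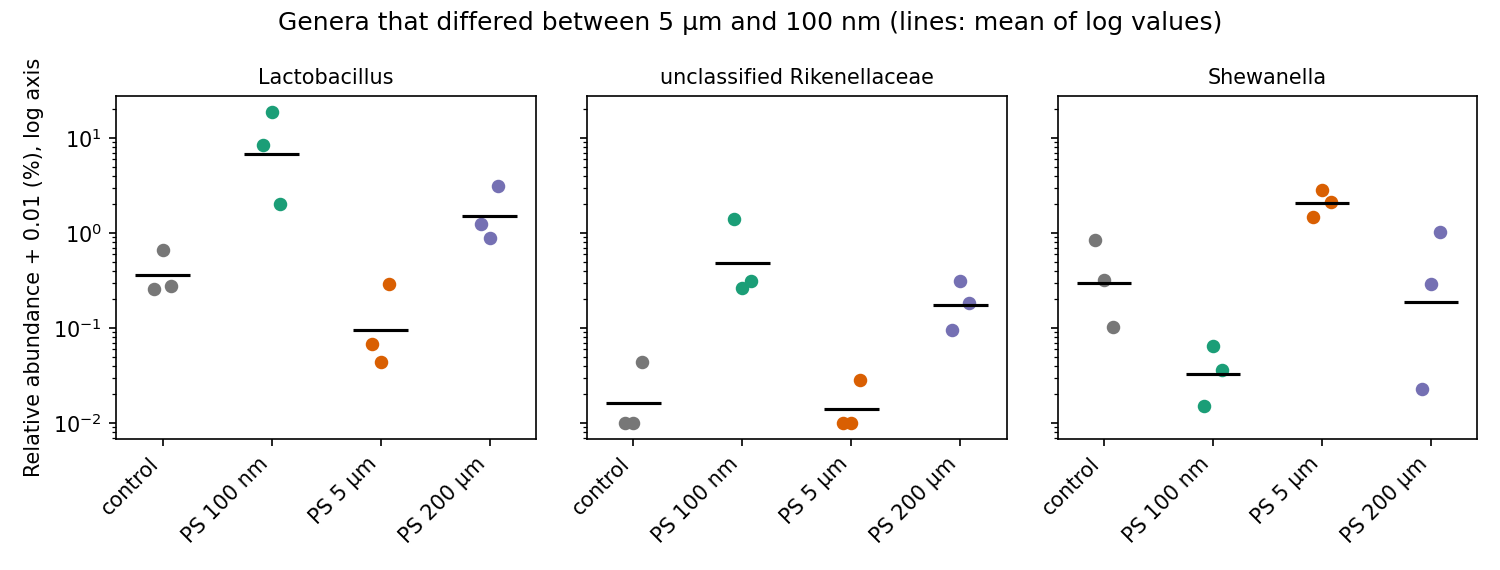
Relative abundance plus 0.01, in percent on a log axis, of Lactobacillus, unclassified Rikenellaceae and Shewanella in each library (points), by exposure group (horizontal axes), with the mean of the log values of each group of 3 as a line. All 3 libraries at 5 µm lay below all 3 at 100 nm for Lactobacillus and unclassified Rikenellaceae, and above them for Shewanella.

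Between 200 µm and 100 nm, Neisseria and Haemophilus, genera of mammalian mouths and airways, held 1.29% ± 2.06 (SD, n = 3) and 1.16% ± 1.68 of the 200 µm libraries against 0.00698% ± 0.00991 and 0.0244% ± 0.0287. Romboutsia held 0.0855% ± 0.117 against 2.32% ± 2.08, a log2 difference of -4.93 with an adjusted p of 0.138. Paraclostridium and Butyricicoccus had log2 differences of -3.72 and -2.99, and the genus label of unidentified bacteria 2.87. Devosia and unclassified Alphaproteobacteria were listed at 0 in the 100 nm libraries, and unclassified Solirubrobacterales and unclassified Moraxellaceae in the 200 µm libraries. None of the 267 genera passed limma, and 23 were under an unadjusted p of 0.05, 9 of them higher, against 28, 11 of them higher, with the centred log ratio.

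Between 200 µm and 5 µm, Haemophilus and Prevotella held 1.16% ± 1.68 (SD, n = 3) and 0.460% ± 0.508 of the 200 µm libraries against 0.0131% ± 0.00943 and 0.0131% ± 0.0183, with log2 differences of 4.18 and 4.05. Proteus, at 0.283% ± 0.378, and the genus label of unidentified bacteria, at 0.237% ± 0.140, were listed at 0 in the 5 µm libraries. The unclassified Gammaproteobacteria named above had a log2 difference of 3.83. Shewanella, unidentified Erysipelotrichaceae, Microbacterium, Intrasporangium and Bosea had log2 differences of -3.45, -3.19, -2.28, -1.95 and -1.87. None of the 267 genera passed limma, and 34 were under an unadjusted p of 0.05, 33 of them higher, against 23, 10 of them higher, with the centred log ratio. With library weights limma called 18, all of them higher in the 200 µm libraries. These weights put most of the 5 µm mean on replicates 1 and 2 (7.27 and 3.38, against 0.423 for replicate 3). Replicates 1 and 2 at 5 µm listed the fewest OTUs of all libraries, 235 and 215.

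Over the 4 groups together, none of the 267 genera and none of the 382 OTUs passed limma, against 21 genera and 33 OTUs at an unadjusted p under 0.05. The lowest adjusted p was 0.134 for genera. Counting genera of at least 0.1% mean share, 4 passed, namely Lactobacillus, Romboutsia, Shewanella and unclassified Rikenellaceae, and 1 Lactobacillus OTU passed at the same filter. The F test called 1 genus with the centred log ratio, 2 without the variance trend and 2 with library weights.

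Of the 10 taxon lists tested as sums, none passed over the 4 groups or for exposed against unexposed libraries. Zebrafish gut core genera held 28.6% ± 36.9 (SD, n = 3) of control, 23.9% ± 21.4 of 100 nm, 76.1% ± 17.5 of 5 µm and 39.5% ± 33.3 of 200 µm libraries (exact permutation F, p = 0.498, adjusted p = 0.553). Spore-forming Bacilli and Clostridia held 0.113% ± 0.0694, 2.61% ± 2.23, 0.119% ± 0.109 and 0.192% ± 0.0468 in the same order, with an exact p of 0.00825 and an adjusted p of 0.0825. Of the 5 tested members of this list, 0 passed over all genera for 100 nm against control, and 2, Romboutsia and Paraclostridium, did so adjusted over the list alone. Reagent contaminant genera, which include Bradyrhizobium and Sphingomonas, held 33.5% ± 36.5, 5.54% ± 3.56, 1.42% ± 1.5 and 2.06% ± 0.977, with an exact p of 0.0715 over the groups and 0.0409 for exposed against unexposed libraries (adjusted p = 0.239 and 0.409). Its log2 difference between exposed and control libraries was -2.94, and 0.070 without the control libraries led by Bradyrhizobium or Buchnera. With Bradyrhizobium, unclassified Xanthobacteraceae and Buchnera left out and all libraries kept it was -2.95 (exact p = 0.0364, adjusted p = 0.364). The remaining shares were rescaled there, which raises the other reagent genera of control replicate 2, where Bradyrhizobium had held 70.3%. In control replicate 3, Sphingomonas had held 24.8% before rescaling. The value of -2.95 therefore does not show a reagent excess that is independent of these control libraries. Lactic acid bacteria held 8.50% ± 7.53, 12.5% ± 6.06, 2.05% ± 2.91 and 10.7% ± 6.24 (exact p = 0.0718, adjusted p = 0.239). Opportunistic fish pathogens, such as Aeromonas and Vibrio, held 13.6% ± 9.75, 11% ± 3.21, 14.4% ± 5.97 and 24.0% ± 17.6 (exact p = 0.675). Gut anaerobic fermenters, a list that includes Cetobacterium, had an exact p of 0.223, plastic and aromatic degraders 0.373, biofilm and plastisphere genera 0.280, nitrifiers and aquarium water genera 0.318, and animal intracellular and symbiont genera 0.341. Plastic and aromatic degraders held 0.222% ± 0.110 of control and 0.391% ± 0.326 (SD, n = 9) of exposed libraries, and biofilm and plastisphere genera 0.0611% ± 0.0475 and 0.243% ± 0.342. For 5 µm against 100 nm, Shewanella passed within the core and pathogen lists and Lactobacillus within the lactic acid list, both over all genera and adjusted over the list alone. Adjusted over the list alone, Romboutsia also passed among the fermenters for 100 nm against control and for both size contrasts with 100 nm, Prevotella there for 200 µm against control, Bdellovibrio among the water genera for 200 µm against control and against 100 nm, and Mycoplasma among the symbionts for 100 nm, 200 µm and all exposed libraries against control. Among the spore formers, Romboutsia and Paraclostridium passed in this way for 5 µm and for 200 µm against 100 nm too. Over the 4 groups, Lactobacillus passed among the lactic acid bacteria, Romboutsia among the fermenters and, with Paraclostridium, among the spore formers, and Mycoplasma among the symbionts. None of these passed over all genera in the same comparison. The water list had 1 tested member, Bdellovibrio, so adjusting over that list left its limma p unadjusted. The symbiont list had 3 tested members.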

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

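The comparison of 5 µm with 100 nm was planned, and the tests of explanations and the count over other splits were chosen after the shares had been seen. In one limma fit, the 5 µm against the 100 nm libraries passed for Shewanella (log2 5.98), Lactobacillus (log2 -6.16) and unclassified Rikenellaceae (log2 -5.10), and this test of a difference between groups flagged them. None of the 267 genera passed against control at either size, and the 3 calls fell to 0 in 7 of the 12 fits that left out 1 library, so these calls do not establish that the particle sizes differ in effect.

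A large Cetobacterium share would push down the shares of all other genera in the 5 µm libraries, so these 3 differences were fitted again with Cetobacterium left out and shares rescaled. The smallest of the absolute differences was then 5.03, so this push accounts for only part of the Lactobacillus difference. The Cetobacterium shares fix how far rescaling moves a difference, so the refit was bound to leave most of differences this large. Shewanella was higher at 5 µm, the opposite of such a push, so the refit does not test it there. Lactobacillus went from -6.16 (SE 1.47) to -5.03 (SE 1.49) and lost its call at an adjusted p of 0.133, because its difference was smaller at a like SE, while Shewanella (7.30) and unclassified Rikenellaceae (-5.19) were called. Of 16 tested fermenter genera, as a mammalian gut would bring to the 100 nm libraries, 15 were lower at 5 µm with a median log2 difference of -1.85, against 74.5% of the 251 other genera with a median of -0.92. With the centred log ratio 13 of 16 were lower (median -0.88) against 48.2% of the others (0.042), and with Cetobacterium left out 14 of 15 (-1.38) against 62.9% of 286 (-0.49), so the list had the lower median each time. This explanation cannot be told apart from an effect of particle size, which remains open and untested, because the median lies short of the -2 set for it and the test compares the same groups that differ in particle size. The labels gave 3 calls and 1 of the 10 splits of the 6 libraries gave as many, with 0 as the highest of the others, and 10 splits are too few for a share under 0.05.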

How the results depend on the processing

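The alternatives without unidentified Cyanobacteria, without Bradyrhizobium, unclassified Xanthobacteraceae and Buchnera, without Cetobacterium, without the pair of control libraries led by Bradyrhizobium or Buchnera, and with shuffled centroid distances were chosen after seeing the data. A fit without chloroplast and mitochondrial OTUs, set before the data were examined, was not run, because 0 OTUs carried such a name. The missing name does not exclude such reads. The set of unidentified Cyanobacteria takes in any Cyanobacteria OTU with the species name Persicaria minor, a flowering plant. Whether the shares filed under Cyanobacteria hold plant reads was not tested. Of 390 alternative values of the 17 comparison results, 342 kept their side of the threshold or a like count (2 or 4 in place of 3 was taken as kept), 18 passed where the reported value had not or rose further in number, and 30 failed where it had passed or fell further in number. All 30 belonged to the only results that had passed, the genera called between particle sizes and the phylum label called over the groups. A result that had not passed could not fail, so the 342 kept values do not measure how well the passing results held. The cause was not tested for any change given here, except where fewer libraries or another number of genera entered the fit. Depth is unknown, so its limit on rare taxa was not computed, and where 1 control library remained it was taken to vary like the other groups.

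For 5 µm against 100 nm, the count of 3 genera became 0 with a pseudocount of 0.001% or 0.1%, with no filter on the mean share, with named OTUs only, with only the 2 groups compared, without the Bradyrhizobium set and without both such control libraries. It became 1 (Shewanella) with the centred log ratio, 2 without Cetobacterium, 4 at a mean share of at least 0.1% and 8 with library weights. Leaving out each library gave 0 to 3, with 0 for control replicate 1, 100 nm replicates 1, 2 and 3, 5 µm replicates 1 and 2 and 200 µm replicate 2, and 2 for 5 µm replicate 3. At a mean share of at least 0.1% the counts were 4 for 100 nm against control and 4 genera and 1 OTU over the groups. Without the variance trend they were 2 for 100 nm against control and 2 over the groups. With library weights they were 3 for 5 µm against control, 18 for 200 µm against 5 µm and 2 over the groups. The weights were highest for 5 µm replicates 1 and 2, so these counts lean on them. With the centred log ratio the count was 1 over the groups. Without both control libraries 1 OTU passed. The centred log ratio sets the mean of all genera to 0 in each library, so a median difference near 0 follows from its construction. The median log2 difference of the 267 genera was 0.72 for 100 nm, -0.23 for 5 µm and 0.73 for 200 µm against control, 0.49 for all exposed, -0.97 for 5 µm against 100 nm and 0.97 for 200 µm against 5 µm. With Cetobacterium left out (301 genera) it was 0.50, 0, 0.73, 0.48, -0.54 and 0.78 in the same order. For 100 nm against control, leaving out each library gave 0 to 3, with 3 without 100 nm replicate 2.

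The count of 1 phylum label became 0 with a pseudocount of 0.1%, with untransformed percent, without the Bradyrhizobium set and without both control libraries, and ran from 0 to 2 when each library was left out. The exact permutation p of composition was 0.0482 with square-root shares, 0.0336 with Aitchison distances and 0.0203 without Cetobacterium, and ran from 0.0323 (without control replicate 1) to 0.387 when each library was left out. That of the spread within groups was 0.00195 with shuffled distances.

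The replicate numbers showed no clear pairing of the libraries, although 3 libraries per group cannot exclude one. Deviations of 18 same-numbered pairs correlated at -0.255 to 0.146 (median -0.0230), and 4 pairs were above 0.1. Those of 36 pairs with different numbers correlated at -0.233 to 0.256 (median 0.0363), and 9 were above 0.1. With the replicate number as a block, the count for 5 µm against 100 nm became 0 and that of phyla 0, and composition had an exact permutation p of 0.238. The block changed no other count of calls.

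Differences between exposed and control libraries that did not pass a test changed sign in places, in log2 units unless stated. Without both control libraries they were 0.44 for Proteobacteria, -1.66 for Fusobacteria, -0.61 for Bacteroidetes, -1.30 for zebrafish gut core genera, -0.28 for fish pathogens, -1.21 for fermenters, 0.070 for reagent genera, 0.97 for nitrifiers and water genera, 0.54 for Rickettsia and 0.67 for Buchnera. Without the Bradyrhizobium set they were -0.075 for Firmicutes, -0.15 for Bacteroidetes, -0.49 for Chloroflexi, -0.48 for unidentified bacteria, -0.49 for Thaumarchaeota, -0.73 for Verrucomicrobia, -0.31 for fish pathogens and -0.66 for plastic degraders. With a pseudocount of 0.001% they were -0.014 for Chloroflexi, -0.091 for unidentified bacteria, -0.61 for Thaumarchaeota, -0.16 for Verrucomicrobia and 0.14 for nitrifiers and water genera. Without Cetobacterium they were 0.11 for lactic acid bacteria and 0.14 for nitrifiers and water genera. That of Cyanobacteria was -0.21 without their unidentified OTUs, that of symbionts -0.188 percentage points when untransformed, and that of the OTU number -3.78 genera at genus level.

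Leaving out each library, the differences ran from -0.059 to 1.11 for Chloroflexi, -0.16 to 0.65 for Thaumarchaeota, -0.32 to 0.86 for Verrucomicrobia, -0.016 to 2.25 for core genera, -0.41 to 1.12 for fish pathogens, -1.35 to 0.56 for lactic acid bacteria, -0.15 to 0.64 for plastic degraders, -0.89 to 0.97 for nitrifiers and water genera and -21.8 to 67.5 for the OTU number. They ran from -3.54 to 0.12 for Rickettsia and -4.53 to 0.76 for Buchnera, and for Buchnera at 5 µm against control from -5.29 to 0.0036.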

Other observations

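The correlations, the tests of sources and the counts over other splits were chosen after the shares had been seen. The shares of 5 taxa, picked after they had been seen, were correlated with those of Cetobacterium across the 12 libraries, on log2(percent + 0.01). Unidentified Erysipelotrichaceae and Shewanella had adjusted permutation p-values under 0.05 by both Pearson's r and Spearman's rho. Aeromonas and Plesiomonas had them by r alone, and Vibrio by neither. Pearson's r was 0.855 for unidentified Erysipelotrichaceae (permutation p = 0.00081, adjusted p = 0.00405) and Spearman's rho was 0.853 (permutation p = 0.00095, adjusted p = 0.00475), over 5 relations computed with 100000 permutations. The adjustment covers only these 5 picked taxa and not the choice among 266 genera, so it does not establish which genera correlated. Most of this taxon is OTUs with a species name of Cetobacterium in the file (median 95.6%), so whether the relation is between different bacteria is open. For Shewanella r was 0.739 and rho 0.797 (adjusted permutation p = 0.0148 and 0.00682), for Aeromonas 0.736 and 0.629 (0.0142 and 0.0533), for Plesiomonas 0.672 and 0.524 (0.0204 and 0.104), and for Vibrio 0.318 and 0.350 (0.324 and 0.266). Without 200 µm replicate 1 and control replicate 3, the libraries farthest from the median, r was 0.829, 0.678, 0.599, 0.432 and 0.490 in the same order, so the relation with Plesiomonas rests partly on them. Over all 266 other genera the median r was -0.245, and 0, 1, 2, 3 and 10 of them had a higher r than these taxa in the same order. With the group means removed r was 0.850, 0.840, 0.875, 0.615 and 0.292, so for unidentified Erysipelotrichaceae, Shewanella and Aeromonas the relation held within groups.

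Of 7 genera on a list of aphid symbionts, 5 were detected, and all 5 were higher in control replicate 3 and in 200 µm replicate 1 than in each of the other 10 libraries. Buchnera held 31.5% and 2.52% of these libraries, Rickettsia 1.60% and 0.173%, Wolbachia 1.49% and 0.188%, Arsenophonus 0.973% and 0.0654%, and Serratia 0.911% and 0.324%. These libraries had drawn attention by their Buchnera shares, and the list was written after the shares had been seen. Buchnera therefore adds no support of its own. The ratios of these genera between the libraries ran from 2.81 to 14.9, where 1 source of fixed composition would keep 1 ratio, so a single such source is not shown. A candidate source is aphid material, by feed, water or carry-over between libraries, which these shares do not separate. The libraries belong to different groups, so exposure does not order them.

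Reagent DNA may account for the 70.3% of Bradyrhizobium in control replicate 2. The other genera of the reagent list held 3.15% of that library, between the median of 1.77% and the highest value of 25% in the other 11, which keeps this open. Unclassified Xanthobacteraceae was high in the same 2 libraries as Bradyrhizobium, at 7.14% in control replicate 2 and 1.13% in 100 nm replicate 2. No biological explanation was tested.

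Moraxella and other genera of pig airways held 52.4%, 25.3% and 23.1% of 100 nm replicate 3, 200 µm replicate 1 and 100 nm replicate 1. The Streptococcus OTUs differed between these libraries. OTU_25 held 9.65% of 200 µm replicate 1 and at most 0.238% of the 100 nm libraries. OTU_21 held 4.36% of 100 nm replicate 3 and 0.322% of 200 µm replicate 1. If 1 outside source of fixed composition had reached the libraries, the most abundant Moraxella OTUs would keep 1 ratio. Over the 7 libraries with at least 1% Moraxella, their log2 ratio ran from -2.27 to 2.02, a span of 4.29, which argues against a single such source for all 7. The ratios far from 0 were -2.27 in 100 nm replicate 1, -2.17 in 5 µm replicate 1 and 2.02 in 100 nm replicate 3. In control replicate 3 and the 200 µm libraries they ran from -0.245 to 0.480, so a single source for these libraries stays open. Several sources, and an effect of exposure, stay open.

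Other splits of the libraries were fitted for each count of calls. Where the labels gave 0 calls every split gives as many by construction (100 of 100 over the 4 groups for genera and for OTUs and for exposed against unexposed libraries, 10 of 10 between pairs of groups), so these counts say nothing about chance. The highest of the other splits gave 3 genera and 8 OTUs over the 4 groups, 5 genera for 100 nm against control, 1 for 200 µm against 100 nm, and 0 for 5 µm against control, 200 µm against control and 200 µm against 5 µm. For exposed against unexposed libraries the highest, 17 genera, came from setting apart 100 nm replicates 1 and 3 and 200 µm replicate 1, the libraries richest in airway genera. This split was picked for its count, and the libraries set apart are all exposed. Whether such a structure follows the groups was not tested.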
